A study of Mus musculus with 8 samples.

How the data were processed

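Poly(A) RNA was sequenced from control and Nfia-transduced mouse neural stem/precursor cells 3 days after transduction, with 3 libraries in each group. Per the labels' protocols, mRNA was isolated with poly(A) beads and libraries were made with a directional kit and read on an Illumina instrument. The deposited values are FPKM (fragments scaled by the length of the transcript and by the mapped fragments of the library), 1 value per gene symbol in each library; the unit was read from the values, since the files have no header, and from the tools named. The submitters' processing notes name TopHat, Bowtie version 1, SAMtools, Cufflinks, Cuffdiff and MACS version 1.4, and the mouse build mm10, with no role or order, so which of these made the FPKM values, the gene annotation, any filter and any use of strand are not given in the sources used here. If strand was not used, reads of overlapping antisense genes cannot be told apart. The Flag ChIP and IgG ChIP samples are not analysed here.

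All 6 libraries held the same 23997 symbols in the same order and no symbol was repeated. Of these, 4813 symbols were listed at 0 in all 6 libraries. FPKM depends on the length of the gene model, so short models can reach very high values: microRNA symbols held 4.13% to 5.14% of the FPKM total of a library. FPKM is a share of the library, so an increase of abundant transcripts lowers the values of the others. Whole reads could not be recovered, because the gene lengths used are not known, and no test for counts was run. Relative depth was estimated from 1599 genes with a mean below 0.3 FPKM, whose values in 2 libraries differ by a fixed ratio where each rests on 1 fragment. It lay between 0.760 and 1.11 of control 1, and since the absolute depth is unknown no counting interval is given.

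Genes with a mean of at least 1 FPKM over the 6 libraries were tested (12537 genes). Values were taken as deposited, with no further scaling, and transformed to log2(FPKM + 1). The groups were compared with limma version 3.58.1 in R version 4.3.3 (lmFit and eBayes with a variance trend, two-sided, 4 residual degrees of freedom before moderation), with Benjamini-Hochberg adjustment over the genes tested and an adjusted p under 0.05. An exact permutation test of 3 against 3 libraries cannot give a p below 0.1, so single genes were judged by limma's moderated test, which pools the spread over genes. A gene called at least 2-fold changed also had a log2 difference of at least 1 in size. Fold values of single genes in the text are ratios of mean FPKM. The counts of genes at least 2-fold changed use the log2(FPKM + 1) difference instead, so they leave out some genes whose FPKM ratio passes 2-fold.

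The test, the filter, 29 gene lists and the rule for naming genes were fixed before the data were examined. Named are the NFI family, genes of the largest increases and the 12 largest decreases among called genes whose groups do not overlap, up to 4 members of each list with the smallest adjusted p, and each gene that a list count of 5 or fewer rests on. Predicted genes and small RNA models were passed over (2 among the increases and 1 among the decreases). Lists were tested with camera from limma, which compares a list with the other genes, with a preset correlation of 0.01 and with an estimated correlation, and with fry, adjusted over the 27 lists with at least 3 members tested. The microglia list had 1 member tested and the erythroid list 0. Some genes stand in more than 1 list, such as Gfap, Fgf15, Hes1 and Notch1.

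Gene positions are spans from a RefSeq table of GRCm38.p6, the assembly that mm10 also denotes, matched by symbol for 12490 of the 12537 genes tested. That table holds no exons. The limma step was tested on simulated data of 12537 genes with limma's moderated spread of these libraries and 200 changed genes, in 20 runs for the comparison of Nfia with control. It recovered 73.3% of genes changed by 0.5 on the log2 scale, 96.6% at 1 and 97.3% at 2, and 3.87% of its calls were false. The simulated values were normal with that moderated spread, so they followed the model being tested. The simulated genes varied independently, and far fewer were changed than the 3918 called in the data. These rates therefore need not hold for the real comparison.

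Each result was recomputed with a pseudocount of 0.1, with no filter on low values, with a mean of at least 5 FPKM, with upper-quartile, median-of-ratios and quantile scaling, without a variance trend, with a robust trend, with library quality weights, with the replicate number as a block, and without each library in turn.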

Results

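RNA-seq was carried out on mouse neural stem/precursor cells (NS/PCs), the dividing cells of the embryonic brain that give rise to neurons and glia. The cells came from the telencephalon, the front part of the brain, of E11.5 embryos of the ICR strain. The developmental stage label of the samples gives embryonic day 11 instead. The cells were grown as an adherent culture with 10 ng/mL basic fibroblast growth factor. One group of 3 libraries came from control cells and the other group of 3 libraries from cells transduced with Nfia, which encodes a DNA-binding transcription factor of the nuclear factor I (NFI) family. The RNA was taken 3 days after transduction. The series also has 1 Flag ChIP and 1 IgG ChIP sample, which are not analysed here. The labels do not say whether the 3 libraries of a group came from separate cultures, so the p-values below measure the spread between these libraries, which may be technical. Each library was given as FPKM for 23997 gene symbols, with totals of 474010 to 511700 FPKM. The files hold no read counts. From the steps between low values, the depth relative to control 1 was 0.906 in control 2, 0.912 in control 3, 1.11 in Nfia 1, 0.911 in Nfia 2 and 0.760 in Nfia 3, and the absolute depth is unknown. The comparison asked which genes respond to Nfia in these cells. Log2 differences are Nfia minus control on the log2(FPKM + 1) scale, which understates the change of genes with low values, and adjusted p-values are from limma with Benjamini-Hochberg adjustment over 12537 genes.

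Nfia itself was 22.0 ± 2.06 FPKM in control and 86.1 ± 17.2 FPKM in Nfia-transduced cells (SD, n = 3 per group), 3.92-fold higher. The control libraries held 19.8, 23.9 and 22.2 FPKM and the Nfia libraries 69.0, 85.6 and 103.5 FPKM (log2 difference 1.91, SE 0.14, adjusted p = 0.000413). The gene lies on chromosome 4 from 97578066 to 98118876 in GRCm38, and the values do not separate the endogenous transcript from the introduced one. Nfic rose from 5.64 ± 0.652 to 9.16 ± 0.955 FPKM (log2 difference 0.61, SE 0.10, adjusted p = 0.00512). Nfix rose from 15.9 ± 2.76 to 24.0 ± 3.15 FPKM (log2 difference 0.57, SE 0.14, adjusted p = 0.0228), a call that ended without control 3, Nfia 2 or Nfia 3 (adjusted p = 0.0552, 0.0781 and 0.0776). Nfib was 63.6 ± 3.50 FPKM in control and 61.2 ± 3.87 FPKM with Nfia, a difference that did not pass the test (adjusted p = 0.534). As a list the NFI family, with 3 of 4 members higher over all genes and 3 adjusted over the list alone, did not pass camera (adjusted p = 0.0847). It passed without Nfia 1 (adjusted p = 0.0498) and with no filter on low values (adjusted p = 0.0464), but not with an estimated correlation (adjusted p = 0.938, and 0.851 with no filter). Nfia, the transduced gene, is itself a member of the list and had the largest log2 difference in it. The count and these tests therefore do not show a response of the family apart from Nfia. The family shares a conserved DNA-binding domain, and no source states how reads that fit more than 1 member were assigned.

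**Figure D1:**
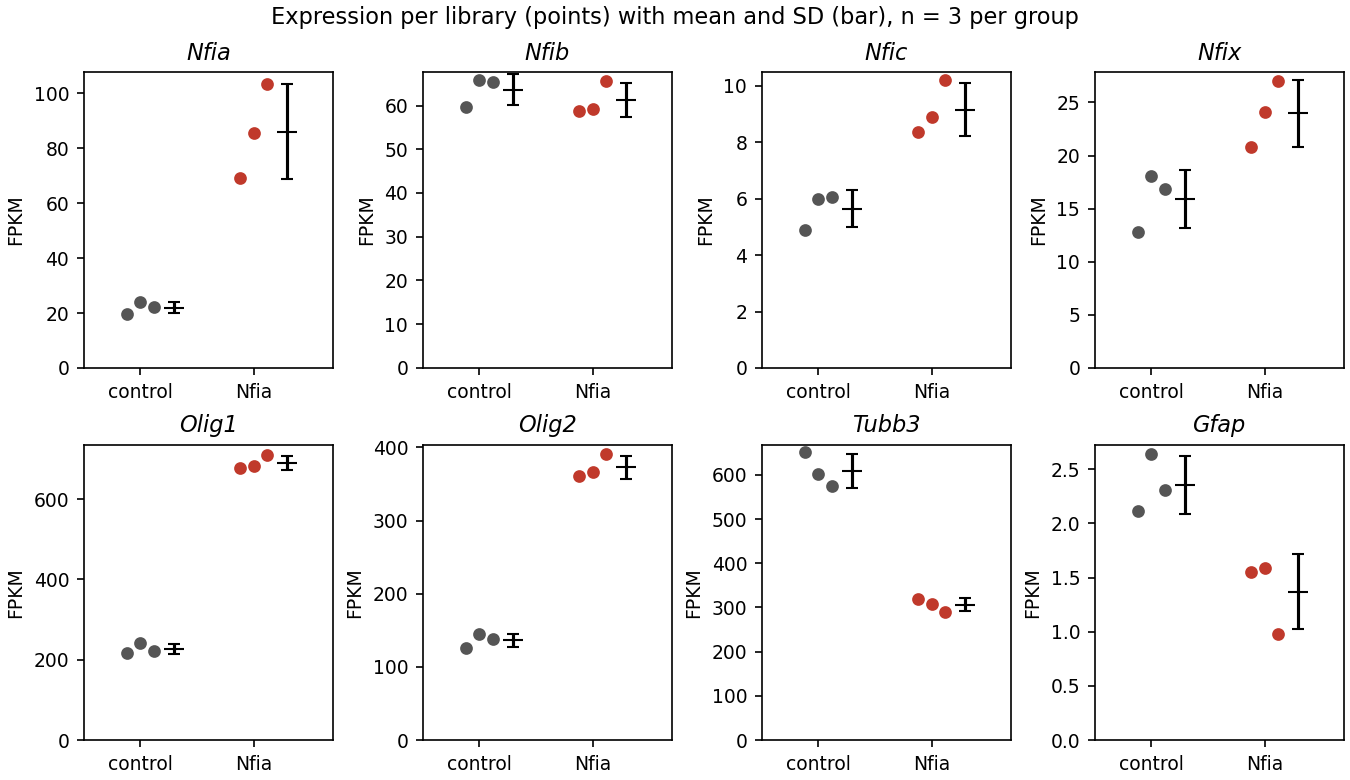
FPKM in each of the 3 control and 3 Nfia libraries (points) with the group mean and SD (bar) for the 4 NFI genes and for Olig1, Olig2, Tubb3 and Gfap; each vertical axis starts at 0 and has its own range. The Nfia libraries lie above all control libraries for Nfia, Nfic, Nfix, Olig1 and Olig2 and below them for Tubb3 and Gfap, while Nfib overlaps.

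Across the 12537 genes tested, 2020 were higher and 1898 lower with Nfia at an adjusted p under 0.05. The counts of higher and lower list members below are to be read against these shares of all genes. A list count near them is not particular to the list. Of all genes tested, 114 were called at least 2-fold higher and 31 at least 2-fold lower on the log2(FPKM + 1) scale. With a pseudocount of 0.1 these counts were 178 and 93. At a mean of at least 5 FPKM, 20 were at least 2-fold lower. The median log2 difference of all genes was 0.01. In 5976 genes (47.7%) the Nfia libraries all lay above or all below the control libraries, against 10% by chance for 3 against 3. The first principal component held 30.7% of the variance and separated the groups. Correlations were 0.949 to 0.961 within groups and 0.934 to 0.948 between them, over genes, which are not independent replicates. Without Nfia 2 the calls fell to 1290 higher and 1251 lower.

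The largest increases named here included genes of secreted and cell-surface proteins. Wfdc2, a secreted protein of the whey acidic protein family, rose 12.8-fold from 1.78 ± 0.484 to 22.8 ± 12.6 FPKM (log2 difference 2.92, SE 0.45, adjusted p = 0.0043). Ngfr, the p75 neurotrophin receptor gene, rose 9.43-fold to 18.3 ± 4.69 FPKM. Thy1, a surface glycoprotein, rose from 0.419 ± 0.0178 to 7.35 ± 2.21 FPKM. Dio2, the deiodinase that activates thyroid hormone in astrocytes, rose 9.27-fold to 9.68 ± 1.24 FPKM (log2 difference 2.38, SE 0.10, adjusted p = 9.12e-05). The others named were Ccdc80 (log2 difference 2.43), the uridine phosphorylase gene Upp1 (2.23), the homeobox gene Dbx2 (2.14), Lynx1 (2.12), Ier3 (2.11), the extracellular matrix gene Npnt (1.95) and Rap1gap (1.91). In GRCm38, Wfdc2 lies on chromosome 2 from 164562715 to 164568510 and Dio2 on chromosome 12 from 90724552 to 90739038. Each of these calls held when any 1 library was left out.

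The 12 largest decreases named included genes of calcium-binding proteins and signalling ligands. Gmnc, a regulator of multiciliated cell formation, fell from 6.82 ± 0.694 to 1.71 ± 0.0898 FPKM (log2 difference -1.52, SE 0.09, adjusted p = 0.000179). The calcium-binding protein genes Scgn and Calb1 fell from 7.94 ± 1.10 to 2.22 ± 0.363 FPKM and from 10.2 ± 0.760 to 3.37 ± 0.283 FPKM. Fgf15, a fibroblast growth factor of the early forebrain, fell from 33.2 ± 1.67 to 12.1 ± 1.18 FPKM (log2 difference -1.38, SE 0.08, adjusted p = 0.000174). Tac1, the substance P precursor gene, had a log2 difference of -1.42, Sema3e, a guidance ligand, -1.31, and the LIM homeobox gene Isl1 -1.23. Asb4 (-1.36), Slc27a2 (-1.26), Gstm7 (-1.22) and Zcchc12 (-1.18) completed the group with Wnt8b, a Wnt ligand of the medial cortex. Wnt8b fell from 9.23 ± 2.36 to 3.52 ± 1.27 FPKM (log2 difference -1.19), and its call ended without control 2 or control 3 (adjusted p = 0.0573 and 0.0588). Gstm7 belongs to a family of closely similar genes, so its value is uncertain where reads were split between copies. Gmnc lies on chromosome 16 from 26957235 to 26991675 and Fgf15 on chromosome 7 from 144896532 to 144900953 in GRCm38.

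**Figure D2:**
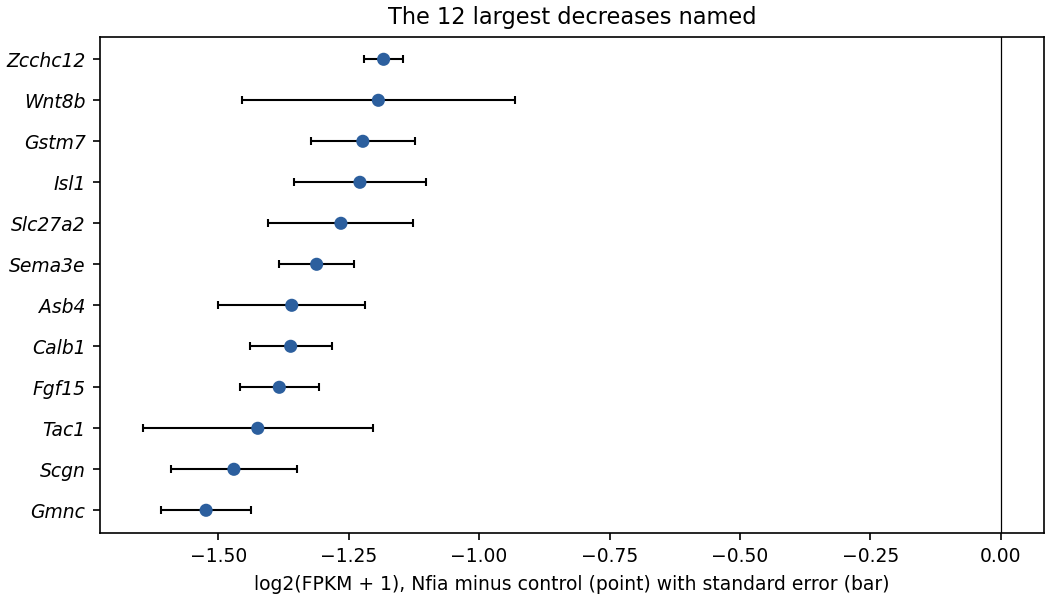
Log2 difference of FPKM + 1, Nfia minus control (points), with its standard error (bars), for the 12 largest decreases named. They run from -1.52 to -1.18.

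Most neuron genes were lower with Nfia. Of 32 neuron genes tested, 25 were lower and 2 higher, and adjusted over the list alone 26 were lower and 2 higher. Tubb3, the neuronal beta-tubulin, fell from 609 ± 38.8 to 306 ± 14.7 FPKM (log2 difference -0.99, adjusted p = 0.000318), and Dcx, a microtubule-associated protein of young neurons, from 131 ± 8.71 to 79.7 ± 2.63 FPKM (log2 difference -0.71). The neuronal RNA-binding protein genes Elavl4 and Elavl3 had log2 differences of -0.77 and -0.55. The members that rose were Dpysl3 (log2 difference 0.41) and the neurofilament gene Nefl (0.31). The call of Nefl ended without Nfia 2 or Nfia 3 (adjusted p = 0.0686 and 0.0562), each of which left 1 of the list's genes higher. As a list they passed camera with its preset correlation (adjusted p = 1.41e-10) but not with an estimated correlation (adjusted p = 0.338).

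Genes of the ventral telencephalon and of GABA neurons, the inhibitory neurons born there, were mostly lower. Of 16 tested, 14 were lower and 0 higher (15 lower and 0 higher adjusted over the list alone), with a mean log2 difference of -0.71. The homeobox genes Dlx1 and Dlx5, which drive the formation of these neurons, fell from 97.7 ± 4.22 to 54.4 ± 5.19 FPKM (log2 difference -0.84) and from 63.3 ± 4.35 to 31.4 ± 4.15 FPKM (log2 difference -0.99, adjusted p = 0.000886). Gad2, an enzyme of GABA synthesis, fell from 21.8 ± 1.94 to 12.7 ± 0.716 FPKM. By camera the list passed (adjusted p = 8.24e-09), but not with an estimated correlation (adjusted p = 0.586).

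Among 14 neurogenic progenitor genes, 7 were lower and 1 higher, with the same counts adjusted over the list alone. Neurog2 and Eomes, regulators of excitatory neuron formation, fell from 6.45 ± 0.380 to 3.50 ± 0.484 FPKM (log2 difference -0.73) and from 8.40 ± 1.58 to 3.89 ± 0.618 FPKM (log2 difference -0.94, adjusted p = 0.00393). Elavl2 fell by 0.52 on the log2 scale. By camera the list passed (adjusted p = 0.00214) but not with an estimated correlation (adjusted p = 0.667).

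Neural stem cell and radial glia genes went both ways. Of 24 tested, 12 were lower and 6 higher (12 and 8 adjusted over the list alone), and the list did not pass camera (adjusted p = 0.425). Nes, the intermediate filament nestin, rose from 91.4 ± 5.67 to 149.8 ± 4.83 FPKM and Notch1 from 17.3 ± 1.73 to 35.9 ± 4.04 FPKM (log2 difference 1.01, adjusted p = 0.000838). Pax6, a regulator of dorsal radial glia, fell from 17.6 ± 1.44 to 10.9 ± 0.376 FPKM and Dach1 from 10.8 ± 0.437 to 4.79 ± 0.171 FPKM (log2 difference -1.02). Among 10 genes of early-gestation precursors, 3 rose and 3 fell (5 and 3 adjusted over the list alone; camera adjusted p = 0.984). Those that fell were Fgf15, the Notch-related ligand gene Dlk1 (log2 difference -0.61) and Nr2f2 (-0.32). Those that rose were the RNA-binding protein genes Igf2bp3 (0.23) and Igf2bp2 (0.27) and the chromatin protein gene Hmga2 (0.57). The call of Igf2bp2 ended without control 3 (adjusted p = 0.0525), and that of Nr2f2 without control 1 or 3 (adjusted p = 0.0579 and 0.0674). That of Hmga2 ended without control 1, control 3, Nfia 2 or Nfia 3 (adjusted p = 0.0567, 0.0513, 0.066 and 0.0533).

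Astrocyte genes also went both ways, with more of them higher. Of 36 tested, 15 were higher and 7 lower (15 and 9 adjusted over the list alone). Mfge8, a secreted glycoprotein, rose from 33.3 ± 2.06 to 117.0 ± 3.29 FPKM (log2 difference 1.78, adjusted p = 7.76e-05), and Sparcl1, a secreted matrix protein of astrocytes and their precursors, from 44.2 ± 2.94 to 105.0 ± 6.92 FPKM (log2 difference 1.23). Dio2 and the hyaluronan receptor gene Cd44 (log2 difference 0.85) also rose. Gfap, the intermediate filament used as a marker of astrocytes, was low in both groups and fell from 2.36 ± 0.267 to 1.37 ± 0.342 FPKM (log2 difference -0.51, adjusted p = 0.0308). Its call ended without control 1, control 2 or control 3 (adjusted p = 0.0506, 0.0856 and 0.075). The members S100b and Aqp4 were below the filter, at a mean of 0.588 and 0.483 FPKM over the 6 libraries. The list did not pass camera (adjusted p = 0.0981). Without control 2 it passed (adjusted p = 0.0231) but not with an estimated correlation (adjusted p = 0.366, and 0.986 with all libraries), and 4 in place of 7 members were then lower.

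Oligodendrocyte lineage genes went both ways, with large increases of 3 transcription factor genes. Olig1 and Olig2, neighbouring genes for basic helix-loop-helix factors of oligodendrocyte and ventral progenitors, rose from 227 ± 13.5 to 689.6 ± 18.5 FPKM (log2 difference 1.60, SE 0.06, adjusted p = 9.12e-05) and from 136 ± 9.48 to 373 ± 15.6 FPKM (log2 difference 1.45, SE 0.07, adjusted p = 0.00011). They lie on chromosome 16 from 91269769 to 91271939 and from 91225550 to 91228677 in GRCm38. Sox8 rose from 23.7 ± 2.05 to 59.3 ± 1.86 FPKM (log2 difference 1.29), and Nkx2-2 from 0.791 ± 0.213 to 1.58 ± 0.242 FPKM (log2 difference 0.53). Pdgfra, the receptor of oligodendrocyte precursors, fell from 7.0 ± 0.0540 to 4.14 ± 0.448 FPKM and Mbp, the myelin basic protein gene, from 5.57 ± 0.721 to 3.32 ± 0.401 FPKM. In total 4 of 14 tested were higher and 2 lower (4 and 3 adjusted over the list alone), and the list did not pass camera (adjusted p = 0.799). The call of Nkx2-2 ended without control 1, control 3 or Nfia 2 (adjusted p = 0.0607, 0.0683 and 0.0512).

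Many cell cycle genes were higher with Nfia. Of 36 tested, 21 were higher and 0 lower (24 and 0 adjusted over the list alone), with a mean log2 difference of 0.26. The cyclin D1 gene Ccnd1 rose from 169 ± 15.1 to 311 ± 8.85 FPKM (log2 difference 0.88, adjusted p = 0.000488). Smaller increases were seen for Rrm2 (log2 difference 0.44), Cdk1 (0.32) and the cyclin A2 gene Ccna2 (0.29). As a list they passed camera (adjusted p = 9.76e-07) but not with an estimated correlation (adjusted p = 0.231). The count of higher members was 10 without control 1, 10 without control 3, 8 without Nfia 2 and 12 without Nfia 3, and under upper-quartile scaling 14 were higher and 1 lower. Among 21 CDK inhibitor and p53 target genes, 4 rose and 3 fell (5 and 4 adjusted over the list alone; camera adjusted p = 0.77), and 3 rose and 5 fell under upper-quartile scaling and under quantile normalization. Cdkn1c, the gene of the CDK inhibitor p57, fell from 45.6 ± 4.38 to 23.9 ± 1.89 FPKM (log2 difference -0.91), as did Pmaip1 (-0.47) and the p27 gene Cdkn1b (-0.15). Plk2 (0.59), Gdf15 (1.10), Eda2r (0.37) and Aen (0.20) rose. The call of Cdkn1b ended when any 1 library was left out (adjusted p = 0.0577 to 0.117), and that of Aen without control 1, 2 or 3 or Nfia 2 or 3 (adjusted p up to 0.115).

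Most genes of cholesterol synthesis were higher with Nfia. Of 21 tested, 17 were higher and 0 lower (18 and 0 adjusted over the list alone). Idi1, an isomerase of the pathway, rose from 69.8 ± 3.46 to 99.5 ± 3.31 FPKM (log2 difference 0.51, adjusted p = 0.000981). Insig1, a regulator of sterol synthesis, rose by a log2 difference of 0.45, Stard4, a sterol carrier, by 0.41 and Hsd17b7 by 0.37. The list passed camera (adjusted p = 8.24e-09) but not with an estimated correlation (adjusted p = 0.24).

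Of 23 genes of hypoxia and glycolysis, 12 rose and 2 fell, with the same counts adjusted over the list alone. Ldha, the lactate dehydrogenase A gene, rose from 211 ± 8.62 to 429 ± 13.1 FPKM (log2 difference 1.02, adjusted p = 0.000151) and the aldolase gene Aldoa from 353 ± 14.9 to 522 ± 4.01 FPKM (log2 difference 0.56). Vegfa (0.59) and Egln3 (0.48), both induced by hypoxia, also rose. Bnip3, another hypoxia-induced gene (log2 difference -0.22), and the glucose transporter gene Slc2a3 (-0.42) fell. The call of Slc2a3 ended without control 2 or 3 or any of the 3 Nfia libraries (adjusted p = 0.0805 to 0.134), each of which left 1 member lower. The list passed camera (adjusted p = 0.00203) but not with an estimated correlation (adjusted p = 0.231).

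Of 23 genes of the unfolded protein and integrated stress responses, 12 rose and 4 fell (14 and 4 adjusted over the list alone). The 3 with the smallest adjusted p were genes of amino acid metabolism. Psat1, of serine synthesis, rose from 187 ± 10.7 to 302 ± 2.95 FPKM (log2 difference 0.69, adjusted p = 0.000453), Shmt2 by a log2 difference of 0.56 and Asns by 0.46. The stress response factor gene Xbp1 rose by 0.25. Those that fell were the stress-induced genes Dnajb9 (-0.21), Ddit3 (-0.19) and Ddit4 (-0.20) and the cystine transporter gene Slc7a11 (-0.23). The list passed camera (adjusted p = 0.00913) but not with an estimated correlation (adjusted p = 0.416). The count of lower members was 2 without control 3 and 1 without Nfia 1, Nfia 2 or Nfia 3. The calls of Ddit3 and Ddit4 ended without control 3 or any of the 3 Nfia libraries and that of Slc7a11 without any of the 3 Nfia libraries (adjusted p = 0.0505 to 0.0839).

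**Figure D3:**
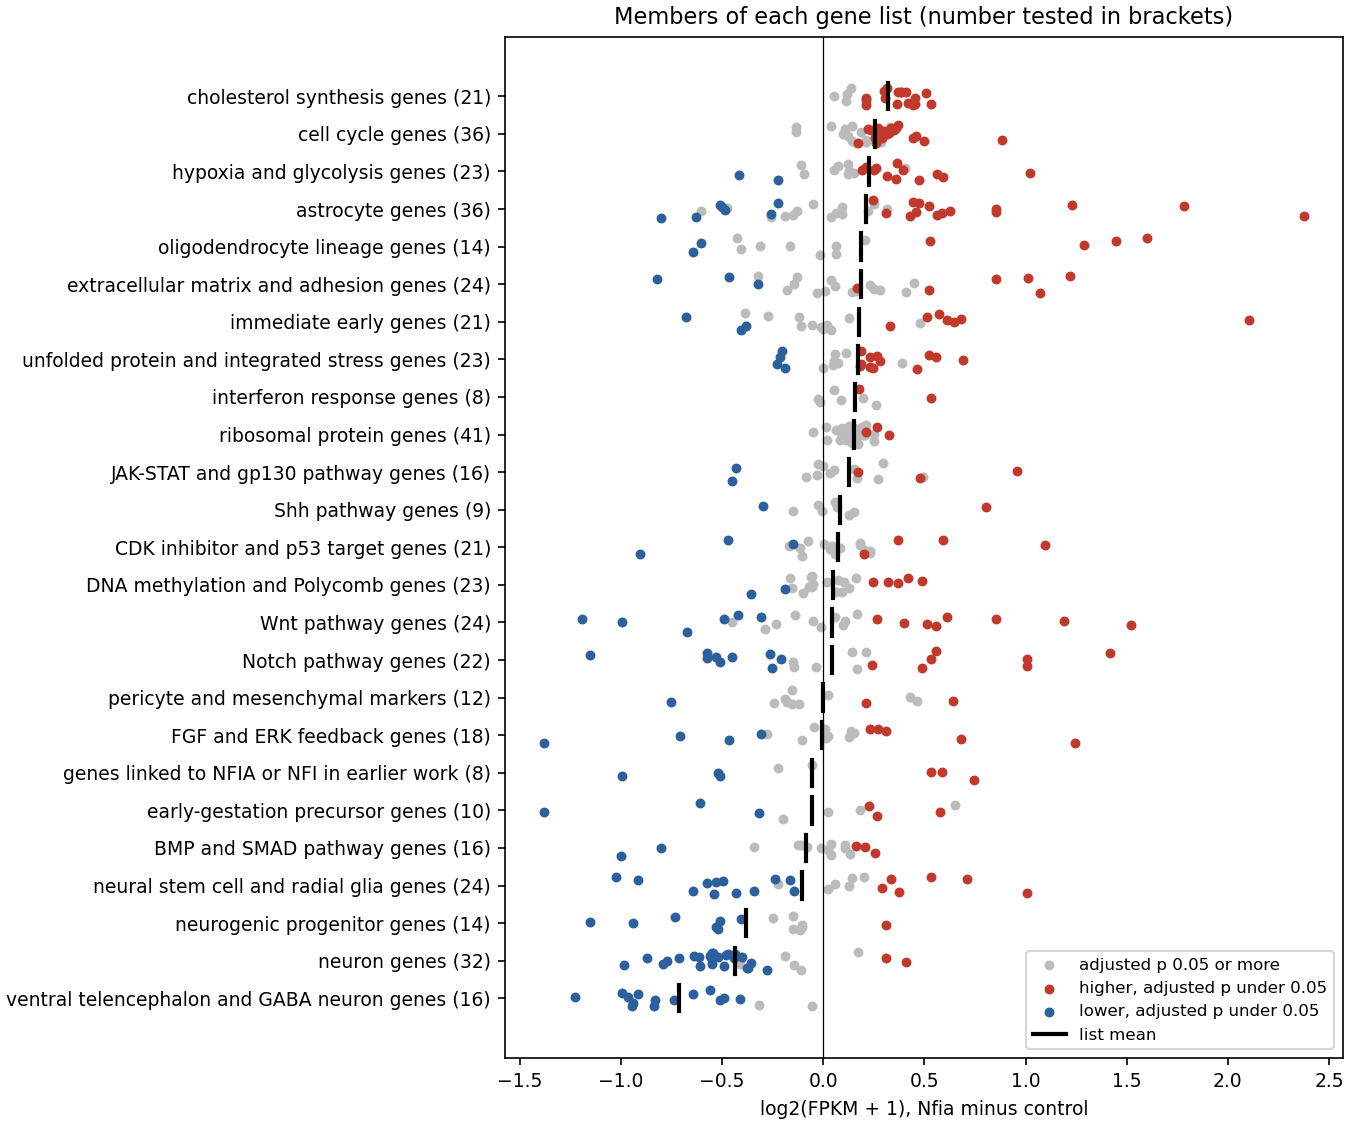
Log2 difference of FPKM + 1, Nfia minus control, of each tested member (points) of the gene lists with at least 8 members tested, with the list mean (black bar); red points were higher and blue points lower at an adjusted p under 0.05. The lists run from a mean of -0.71 for ventral telencephalon and GABA neuron genes to 0.32 for cholesterol synthesis genes.

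Components of several signalling pathways changed in both directions, but their lists did not pass camera, which compares a list with the other genes. Of 22 Notch pathway genes, 7 rose and 9 fell, with the same counts adjusted over the list alone (camera adjusted p = 0.984). Notch1 and Lfng, a glycosyltransferase that modifies Notch, rose, the latter from 26.7 ± 0.559 to 54.8 ± 0.400 FPKM (log2 difference 1.01). The ligand gene Dll4 rose from 0.652 ± 0.0777 to 3.42 ± 0.517 FPKM (log2 difference 1.42), and Nrarp, a target and inhibitor of the pathway, fell by 0.58 on the log2 scale. The count of lower Notch genes was 4 without control 1, 5 without control 2 and 4 without Nfia 2. Of 24 Wnt pathway genes, 8 rose and 6 fell (8 and 7 adjusted over the list alone; camera adjusted p = 0.984). The receptor genes Fzd9 and Fzd5 rose, Fzd9 from 9.34 ± 1.40 to 28.5 ± 1.98 FPKM (log2 difference 1.52) and Fzd5 from 0.985 ± 0.130 to 3.54 ± 0.542 FPKM (log2 difference 1.19), as did Tcf7 (0.85). The Wnt inhibitor gene Apcdd1 fell from 17.2 ± 1.18 to 8.15 ± 0.0543 FPKM (log2 difference -0.99).

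Of 18 genes of FGF and ERK feedback, 5 rose and 4 fell, with the same counts adjusted over the list alone (camera adjusted p = 0.984). Egfr, the epidermal growth factor receptor gene, rose from 18.6 ± 1.05 to 45.3 ± 1.24 FPKM (log2 difference 1.24, adjusted p = 9.12e-05), as did Etv4 (0.68), Fgfr3 (0.31), Spred2 (0.27) and Spry2 (0.23). Fgf15, Dusp4 (-0.71), Spred3 (-0.47) and Etv1 (-0.31) fell. The count of higher members was 2 without control 3 and 3 without Nfia 2. The calls that ended were that of Spry2 without control 3, that of Spred2 without control 1, control 3 or Nfia 2, and that of Fgfr3 without control 3 or any of the 3 Nfia libraries (adjusted p = 0.0505 to 0.0678).

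Of 16 JAK-STAT and gp130 pathway genes, through which astrocyte-inducing cytokines act, 3 rose and 2 fell (4 and 2 adjusted over the list alone; camera adjusted p = 0.514). The receptor gene Lifr rose from 2.69 ± 0.446 to 6.15 ± 0.776 FPKM (log2 difference 0.96), as did Stat3 (0.48) and Jak1 (0.17). The receptor gene Cntfr (-0.43) and the inhibitor gene Socs2 (-0.45) fell. The call of Jak1 ended when any 1 library was left out (adjusted p = 0.0547 to 0.13) and under upper-quartile scaling (0.106), median-of-ratios scaling (0.0603) and quantile normalization (0.0502). Of 16 BMP and SMAD pathway genes, 3 rose and 2 fell, with the same counts adjusted over the list alone (camera adjusted p = 0.984). Id4, an inhibitor of basic helix-loop-helix factors, fell from 48.6 ± 5.17 to 23.7 ± 0.935 FPKM, and the BMP antagonist gene Chrdl1 by 0.80 on the log2 scale. Id1 (0.25), Id2 (0.21) and Smad5 (0.16) rose. No BMP gene was higher without control 3 or Nfia 2 (0 of 16), and 1 was without Nfia 1. The call of Smad5 ended without control 3 or Nfia 2, that of Id1 without control 1 or 3 or Nfia 1 or 2, and that of Id2 without control 2 or 3 or Nfia 1 or 2 (adjusted p = 0.0567 to 0.107). Of 9 Shh pathway genes, the co-receptor gene Cdon rose from 8.63 ± 0.194 to 15.9 ± 0.954 FPKM (log2 difference 0.81) and Gli3 fell (-0.30), giving 1 higher and 1 lower (2 and 1 adjusted over the list alone; camera adjusted p = 0.761). The call of Gli3 ended on leaving out any library other than Nfia 3 (adjusted p = 0.0562 to 0.0805).

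Genes that earlier work links to NFIA or the NFI family were tested as a list of 8, fixed before the data were examined. Slc1a3, the glial glutamate transporter gene, rose from 56.5 ± 2.75 to 85.3 ± 1.75 FPKM (log2 difference 0.59), as did Zcchc24 (0.75) and the Notch effector gene Hes1 (0.53). Apcdd1, Mmd2 (-0.52) and Gfap fell, Gfap not without control 1, control 2 or control 3 (adjusted p = 0.0506, 0.0856 and 0.075). The counts of 3 higher and 3 lower were the same adjusted over the list alone, and the list did not pass camera (adjusted p = 0.984). The list was fixed without an expected direction for each gene, and camera tests for a shift in one direction. These results therefore do not show whether the genes moved as in the earlier work.

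Of 24 extracellular matrix and adhesion genes, 6 rose and 3 fell (7 and 3 adjusted over the list alone; camera adjusted p = 0.349). Ncan, the proteoglycan neurocan gene, rose from 63.8 ± 2.99 to 130.4 ± 14.7 FPKM (log2 difference 1.01), as did Lama5 (1.22) and Tnc (0.86). Cdh6 (-0.82), Vcan (-0.32) and Sparc (-0.47) fell. The call of Vcan ended without control 1 or Nfia 2 (adjusted p = 0.0503 and 0.0549) and that of Sparc without control 2 or 3 or any of the 3 Nfia libraries (adjusted p = 0.0594 to 0.13), and 1 member was lower without Nfia 2. Of 21 immediate early genes, 7 rose and 3 fell, with the same counts adjusted over the list alone (camera adjusted p = 0.557). Ier3, Myc (0.68), Klf6 (0.65) and Jun (0.57) rose, while Fosb (-0.68), Btg2 (-0.41) and Fos (-0.38) fell, Fos not without control 2 or 3 or Nfia 2 or 3 (adjusted p = 0.1 to 0.121).

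Of 23 DNA methylation and Polycomb genes, 5 rose and 2 fell, with the same counts adjusted over the list alone (camera adjusted p = 0.77). The maintenance methylation genes Dnmt1 (log2 difference 0.32) and Uhrf1 (0.37) rose with Mbd2 (0.25), Tdg (0.49) and Gadd45b (0.42), and Tet2 (-0.36) and Rnf2 (-0.19) fell. The count of higher members was 3 without control 2, and 0 were lower without control 1, control 3, Nfia 1 or Nfia 2. The call of Tdg ended without control 2 or 3, that of Gadd45b without control 1 or 2 or Nfia 2 or 3, that of Tet2 without control 1 or 3 or Nfia 1 or 2, and that of Rnf2 on leaving out any library other than control 2 (adjusted p = 0.058 to 0.109). Of 8 interferon response genes tested, 2 rose and 0 fell (1 and 0 adjusted over the list alone; camera adjusted p = 0.389): Gbp3 (0.53) and B2m (0.18). The call of B2m ended on leaving out any library other than Nfia 3 (adjusted p = 0.0658 to 0.114), and under upper-quartile scaling (0.0879), median-of-ratios scaling (0.0502) and quantile normalization (0.0632).

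Ribosomal protein genes had a mean log2 difference of 0.15, with 3 of 41 higher (Rpl6, Rpl13 and Rpl12, log2 differences 0.27, 0.21 and 0.32), 0 lower, and 0 in either direction adjusted over the list alone. The list passed camera (adjusted p = 0.00442) but not with an estimated correlation (adjusted p = 0.986), and not without control 3 or Nfia 1 (adjusted p = 0.0547 and 0.0854). The number of higher members was 1 without control 1, 0 without control 2, control 3, Nfia 1 or Nfia 2, and 12 without Nfia 3. Where they ended, the calls of the 3 named genes had an adjusted p of 0.0544 to 0.0986. With no filter 1 member was higher, with quantile normalization 6 and with library quality weights 11. These genes have many processed pseudogenes, so their values are uncertain where reads were split between copies.

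Few markers of microglia, endothelium and blood reached the filter. Of 16 microglia and leukocyte markers, 1 reached a mean of 1 FPKM: Cd68, also a lysosomal protein of other cells, rose from 3.08 ± 0.239 to 4.10 ± 0.351 FPKM (log2 difference 0.32, adjusted p = 0.029). Its call ended without control 1, control 3, Nfia 1 or Nfia 3 (adjusted p = 0.0652 to 0.0856), and none of the other 15 exceeded a mean of 0.883 FPKM. Of 14 endothelial markers, 3 were tested: Cldn5 fell from 2.09 ± 0.339 to 1.02 ± 0.158 FPKM (log2 difference -0.61, adjusted p = 0.0121), while Ramp2 (log2 difference 0.38, adjusted p = 0.113) and Egfl7 (0.29, adjusted p = 0.147) did not pass. None of the 12 erythroid markers in the files reached the filter, with a highest mean of 0.793 FPKM. Of 12 pericyte and mesenchymal markers tested, Col5a1 (0.64) and Fbln1 (0.21) rose and Rgs5 fell (-0.75), and the counts of 2 higher and 1 lower were the same adjusted over the list alone. The pericyte counts were 0 higher and 0 lower without Nfia 2 or Nfia 3, and 1 higher without control 1 or control 3, where the call of Fbln1 ended (adjusted p = 0.0685 and 0.0701). Without Nfia 2 or Nfia 3 the 3 pericyte calls ended at an adjusted p of 0.0505 to 0.0731. Without control 2 or Nfia 3, 1 endothelial marker was higher. The endothelial and pericyte lists did not pass camera (adjusted p = 0.984 for each).

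Of the 27 gene lists with at least 3 members tested, 5 were higher and 3 lower by camera with its preset correlation of 0.01, and 0 passed with an estimated correlation. By fry, which asks whether the members of a list change and does not compare them with other genes, 15 lists moved on balance in one direction and 26 changed in either direction. The median and the mean log2 difference differed in sign for early-gestation precursor genes (0.10 and -0.06), Notch pathway genes (-0.09 and 0.04), BMP and SMAD pathway genes (0.03 and -0.09) and FGF and ERK feedback genes (0.02 and -0.01). Camera gave the sign of the mean for the early-gestation and BMP lists and the sign of the median for the Notch and FGF lists. It gave a higher direction for pericyte and mesenchymal markers, whose mean was -0.00 and median -0.14. Besides Jak1 and B2m, the calls of Cdkn1b, Aen, Gadd45b, Sparc, Slc2a3, Fos, Cd68, Rpl6 and Rpl12 ended under another scaling, filter, pseudocount, library weighting or variance trend (adjusted p = 0.0502 to 0.0957).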

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

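The alternatives were fixed before the data were examined. Nfia stayed higher and past the threshold under all of them, and the count of lists passing camera stayed within 1.5 times: the log2 difference of Nfia ran from 1.77 to 2.05 and the lists passing from 7 to 9, against 8. The calls shared with the main setting ran from 63.5% of them without Nfia 2 to 99.3% with a pseudocount of 0.1, and 0 genes were called in the opposite direction under any alternative. With a pseudocount of 0.1, 178 genes were higher and 93 lower by at least 2-fold, against 114 and 31, since a smaller pseudocount widens the log2 differences of low genes. At a mean of at least 5 FPKM, 20 were lower by at least 2-fold, with fewer genes tested. Leaving out 1 library gave 1290 to 1625 genes higher and 1251 to 1572 lower, with fewer samples in each fit. Upper-quartile scaling called 1691 genes higher and 2242 lower, 43.0% higher against 51.6%, and with median-of-ratios and quantile scaling too more genes were lower than higher (49.7% and 47.1% higher). Of 148 called genes followed through the alternatives, 37 lost the call on leaving out some library, 12 under some other alternative, and 0 changed sign.

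The lists whose mean log2 difference changed sign were not called in any of these settings, and the cause was not tested apart from the fewer genes or libraries used. Endothelial markers had a mean of -0.0488 with a pseudocount of 0.1, -0.0809 with no filter, -0.00679 with upper-quartile scaling and -0.0247 with quality weights, against 0.0185. With no filter, the Shh pathway mean was -0.0118 and the interferon response mean -0.0154. At a mean of at least 5 FPKM, genes linked to NFIA had a mean of 0.0102, early-gestation precursor genes 0.0281 and Wnt pathway genes -0.0654. Pericyte and mesenchymal markers had a mean of 0.0789 with quality weights. Leaving out 1 library gave means of -0.0645 to 0.101 for endothelial markers, -0.168 to 0.219 for pericyte and mesenchymal markers and -0.0427 to 0.0194 for FGF and ERK feedback genes.

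The libraries share replicate numbers 1 to 3, and the deviations of same-numbered libraries correlated at 0.03, -0.01 and 0.05 across genes, so the numbers were not taken to pair them; not every library correlated best with its own number. With a replicate block, 2130 genes were higher and 1916 lower, 116 and 32 by at least 2-fold, 8 lists passed and the log2 difference of Nfia was 1.91. The block ended the calls of Nkx2-2, Jak1, B2m, Fos and Cd68 among the named genes. The alternative for repeated symbols has no value because no symbol repeats, and a count model was not run. Depth limits the low genes, since Nfia 3 had 0.760 of the depth of control 1.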

Other observations

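The tests of the ventral and glutamatergic neuron genes, of the spread of the ventral list, of the glial share behind Gfap, of reads shared within the NFI family, and of symbol families were chosen after the results were seen; the scaling tests and the splits were planned.

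Genes were grouped by the stem of their symbol into 179 families of at least 8 members, and 4 families passed camera with its preset correlation, while 0 passed with an estimated correlation (adjusted p = 0.883 for each of the 4). Of 19 genes with the stem Nup, components of the nuclear pore, 10 were higher and 0 lower (adjusted p = 0.0412), and the other 9 did not pass. Nup210, a membrane component of the pore whose level differs between cell types, rose from 11.9 ± 0.213 to 18.9 ± 2.18 FPKM (log2 difference 0.61, SE 0.08, adjusted p = 0.00229 in limma, n = 3 per group). The mean of the family stayed above 0 under the 3 other scalings, at a log2 difference of 0.14 to 0.16 against 0.17, although 6 members were higher and 1 lower under upper-quartile scaling and 7 higher and 1 lower under quantile normalization. The family did not pass without control 3 or Nfia 1 (adjusted p = 0.0574 and 0.0817), and 4 members were higher without control 1, control 3, Nfia 1 or Nfia 2.

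Of 12 clustered protocadherin genes with the stem Pcdhb, which code for adhesion proteins of neurons, 4 were lower, 0 higher and 8 did not pass (adjusted p = 0.0467 for the family): Pcdhb7 fell from 2.77 ± 0.214 to 1.68 ± 0.270 FPKM, Pcdhb17 from 5.08 ± 0.552 to 3.53 ± 0.149 FPKM, and Pcdhb19 and Pcdhb3 by 0.30 and 0.37 on the log2 scale. The family did not pass without control 3 or Nfia 1 (adjusted p = 0.0574 and 0.0817) or under upper-quartile scaling or quantile normalization (adjusted p = 0.0695 and 0.0754), and its lower members numbered 2 without control 1, 2 without Nfia 2 and 1 without control 3. Its mean log2 difference was negative in all 3 other scalings (-0.33 to -0.31). These genes are related to each other and at low levels, so their values are uncertain where reads were split. The stem Rpl, of ribosomal protein genes with some pseudogenes and related genes such as Rpl14-ps1 and Rpl7l1, also passed (adjusted p = 0.0412). In it 5 of 48 were higher (Rpl6, Rpl7l1, Rpl12, Rpl13 and Rpl41) and 0 lower. That share of higher genes was below the one over all genes tested (2020 of 12537). The stem Rps passed too (adjusted p = 0.0479), but it mixes ribosomal protein genes with S6 kinase genes, so no direction is given for it. Neither stem passed without control 3, Nfia 1 or Nfia 2 (adjusted p = 0.12 to 0.225). The higher members of Rpl numbered 2 without control 1, 0 without control 2, control 3, Nfia 1 or Nfia 2, and 19 without Nfia 3, and 8 with quantile normalization.

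The 6 libraries can be split into 3 and 3 in 10 ways, which is too few for a share under 0.05. Each of the other 9 splits also puts control and Nfia libraries in the same group. The real difference then enters the spread within groups and part of the contrast, so these splits do not measure what arises by chance. The real split called 2020 genes higher and the highest of the other 9 splits called 4 in 1 direction. The counts were 1898 against 4 for genes lower, 114 against 4 for genes at least 2-fold higher and 31 against 4 for genes at least 2-fold lower. In each case only the real split, 1 of the 10, reached its own count. For the gene lists, the real split had 8 passing camera and another had 10, so 2 of the 10 splits gave as many. Of the 8 lists that passed, 3 of the 10 splits gave a camera p as small as the real one for neurogenic progenitor genes and 5 for ribosomal protein genes. For the neuron, ventral telencephalon, cell cycle, stress response, hypoxia and cholesterol lists the real split alone (1 of 10) gave the smallest p, although 0 to 8 of the other 9 splits also called them. In no other split was a member of any list called (0 in each).

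The first pattern is the fall of neuron and ventral telencephalon genes, which scaling between libraries does not account for, since the mean log2 difference of either list nearest to 0 under the 3 other scalings was -0.441. An even loss of neurons of every type stays open: 5 glutamatergic neuron genes (Neurod1, Neurod2, Neurod6, Tbr1 and Slc17a6) had a mean log2 difference of -0.19 against -0.71 for the 16 ventral genes, a difference of 0.519 (SE 0.245, exact permutation p = 0.2, smallest possible 0.1). That is above 2 standard errors, but Nfia 1 overlapped the controls, and the requirement of no overlap was added after the value was seen. In control 1, 2 and 3 the mean of the glutamatergic genes minus that of the ventral genes was -1.34, -1.09 and -0.943 on the log2 scale. The log2(FPKM + 1) scale understates the change of low genes, which can add to the difference between these sets. The log2 differences of the 32 neuron genes also varied by more than their errors (SD 0.308, median SE 0.0675). That scale, and expression in other cells, can give such a spread under an even loss too. Fewer cells of the ventral lineage cannot be told apart from less of these transcripts per cell in bulk RNA (SD of the 16 log2 differences 0.304), and a change in the fate of the cells with Nfia, which the design names, may also give this pattern and was not tested.

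The second pattern is the fall of Gfap, an astrocyte marker. Scaling between libraries does not account for its direction. Under another pseudocount, no filter and 3 other scalings, its log2 difference nearest to 0 was -0.488. The filter leaves the values of a gene unchanged, and no pseudocount can reverse groups that do not overlap. The pseudocount and filter could therefore not have changed the direction. A lower share of glial cells would lower the genes of the astrocyte list, of which 15 rose and 7 fell. That explanation was still left open because the list did not pass camera (adjusted p = 0.0981), a requirement added after the values were seen. Gfap was at 2.36 FPKM in control, and its call ended without control 1, control 2 or control 3 (adjusted p = 0.0506, 0.0856 and 0.075) at log2 differences of -0.56, -0.45 and -0.52 against -0.51, with fewer libraries in each fit. An effect of Nfia on Gfap itself stays open and was not tested.

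The third pattern is the rise of Nfic and Nfix with Nfia. Reads of the introduced Nfia transcript that also fit its relatives are a candidate source. In FPKM, the increase of Nfic and Nfix together was 18.1% of that of Nfia, 5.49% for Nfic and 12.6% for Nfix. Nfib, a relative too, changed by -3.79% of the increase of Nfia and did not pass the test (adjusted p = 0.534). FPKM depends on the length of the gene model, so these percentages are not shares of reads. The call of Nfix ended without control 3, Nfia 2 or Nfia 3 (adjusted p = 0.0552, 0.0781 and 0.0776). No transcript sequences were used, so shared reads and a response of the genes cannot be told apart.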
